A study of Mus musculus with 7 samples.

How the data were processed

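Messenger RNA levels were measured in eosinophils sorted by flow cytometry from the lungs of BALB/c mice, an inbred strain often used in models of allergic airway inflammation. The cells came from lungs challenged with saline (n = 4 libraries) or with OVA, an egg white protein (ovalbumin) used as the allergen (n = 3 libraries). Per the labels' protocols, RNA was extracted with the RNeasy kit, amplified with a NuGEN Ovation system, converted to sense-strand cDNA and labelled with biotin; the design text states a sort with high purity. Each library was hybridised to 1 array. The labels do not say whether libraries of a group came from separate animals or pools, so p-values measure only the spread between these samples.

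The values are log2 expression levels that the authors deposited after robust multi-array averaging (RMA), per the submitters' processing notes. The RMA version is not given in the sources used here. RMA subtracts background, brings all arrays to a common distribution and summarises the probes of a probe set. It is thus meant to remove a shift shared by most genes of a library before any comparison. The deposited values still differed in spread, with an SD across genes from 1.665 in saline replicate 2 to 1.9 in OVA replicate 3. Shifts between libraries may therefore remain in part. The column names of a deposited annotated table name the mouse gene 1.0 ST array. The value table held 35557 probe sets, and all 35557 were found in the annotated table. That second table also carries 7 value columns whose names match no sample label; they were not mapped to samples and were not used here. Each of those 7 columns equals a column of the value table within 0.0051 log2, with 2 of the 7 in the same place. Reading their running numbers as sample numbers would place saline replicates 3 and 4 with OVA replicate 3, and that split of the libraries called 1 gene. The planned comparison of tables was not run, because the values differ only by rounding. The written design had assumed the annotated table as the source of values, and the value table with columns named by sample was used in its place.

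Gene symbols were brought up to date through a table of reference genes (assembly GRCm38.p6), used for names only. A symbol was found for 16804 probe sets by accession, 1296 by symbol and 676 by synonym, while 981 kept the symbol of the annotated table and 15800 had none. The update changed 3076 symbols. For the 825 genes with several probe sets, the probe set with the highest mean over all 7 arrays was used, which gave 18187 genes. No filter on dim genes was applied. Genes of near-identical families, among them the eosinophil-associated ribonucleases, Chil3, the Ifitm genes, the stefins, the histones and the alpha globins, share probe sequence and their separate values are uncertain.

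Groups were compared with limma (version 3.58.1, R 4.3.3), using lmFit and eBayes with the group as the only term and 2-sided p-values adjusted by the Benjamini-Hochberg method over all 18187 genes. A gene was called at an adjusted p under 0.05, and a log2 difference of 1 or more was counted as 2-fold. On simulated data with the spread of these libraries and 18187 genes, the OVA against saline comparison called 23.9% of genes changed by 0.5 log2, 67.2% of those changed by 1 and 97% of those changed by 2, with 4 false calls. The simulated values were drawn independently for each gene and library, and 67, 67 and 66 genes were changed by 0.5, 1 and 2. Deviations shared by many genes of a library are not in it, so these figures may not carry over to the real libraries. The number of arrays limits the precision.

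Before the data were examined, 38 gene lists were fixed: 26 programs (granule proteins, eosinophil identity, type 2 activation, cytokines, chemokines, chemoattractant receptors, adhesion, MHC class II, MHC class I, interferon response, NF-kappaB, eicosanoids, survival, cell cycle, unfolded protein response, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, immediate early genes, inhibitory receptors, pattern recognition, Fc and complement receptors, tissue remodelling, lung-resident eosinophil genes, oxidase and proteases, lipid handling) and 12 marker lists of other cell types (alveolar macrophages, monocytes, neutrophils, T, B and NK cells, dendritic cells, mast cells, epithelium, endothelium, fibroblasts, erythroid cells with platelets). Each list was tested with camera (limma) at a preset correlation of 0.01 between genes, adjusted over the 38 lists, and again with a correlation estimated from the data. The level of each list per library, the mean log2 value of its members, was compared by an exact permutation test over the 35 splits of the 7 libraries, 2-sided, whose smallest p is 0.02857. Genes named in the text follow a rule fixed at the same time: the 12 largest called changes in each direction with no overlap between groups, up to 4 called members of each list (up to 2 members where none was called), and 20 genes fixed by name. Genes known only by clone names were passed over, and a few other genes that the rule picks are not reported here, though counts include them. Other list members named in the text (among them Ear1, Ear2, Tgm2, Hbegf, Igf1, Vcam1, Nod1, Fcgr3, Xaf1, Bcl2l11, Pmaip1, Birc3, Dusp5, Abca1, Adam8, Ngp, Marco, Fabp4, Siglec1, Cidec, Serpinb1a, S100a8 and S100a9) were chosen after their values were seen.

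Alternatives fixed beforehand were a replicate block, quantile normalization again, median centring, cyclic loess, a filter at the 30th percentile of mean expression, the mean of all probe sets, every probe set on its own, eBayes with trend and robust, array weights, each library left out in turn, other list tests, limma's treat at a 1.5-fold limit and an unmoderated comparison per gene. Correction of scanner intensities and a block by scan date were not run, because the files used here hold neither. After the data were seen, analyses without saline replicates 1 and 2, without saline replicates 3 and 4, with each array's separation of control probe sets as a covariate, and of 308 biological process terms of the deposited annotation were added. Figures were drawn with matplotlib (version 3.10.9, Python 3.11.15).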

Results

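Expression was measured in 7 libraries of sorted lung eosinophils, granulocytes that accumulate in the airways during allergic inflammation: 4 from saline challenged and 3 from OVA challenged lungs. The comparison asks how the expression profile of these cells differs after allergen challenge. Levels are log2 RMA values, given as mean ± SD over libraries, and differences are OVA minus saline with their standard error (SE). The median level per library lay between 6.61 and 6.72. Negative control probe sets had a median of 5.91 ± 0.04 in saline (n = 4) and 6.09 ± 0.07 in OVA (n = 3; two-sided exact permutation p = 0.02857, the smallest that 35 splits can give).

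The 3 OVA libraries resembled each other closely, with correlations across genes of 0.9904 to 0.9936, against 0.9738 to 0.9898 among the saline libraries and 0.9557 to 0.9787 between groups. The first principal component held 54.3% of the variance and parted the groups, and the next held 21.1%. Within saline, deviations from the group mean correlated at 0.106 between replicates 1 and 2, at 0.25 between replicates 3 and 4 and at -0.53 to -0.68 across these pairs. Deviations of 4 libraries from their own mean give about -0.33 on average by construction, and the 6 values averaged -0.33. The area under the curve that separates positive from negative control probe sets was 0.81 and 0.80 in saline replicates 1 and 2, and 0.843 and 0.845 in saline replicates 3 and 4. Its mean was 0.824 ± 0.0228 in saline (n = 4) and 0.843 ± 0.0123 in OVA (n = 3; two-sided exact permutation p = 0.286). Below, libraries are named by group and replicate number, as in saline 1, and values in brackets after a left-out library are the adjusted p without it, by limma for genes and by camera for lists. Saline 1 and 2 were left out together as a choice made after seeing the data. No library pair looked like a repeat, as the SD of the difference between libraries of a group was 0.215 to 0.447.

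**Figure D1:**
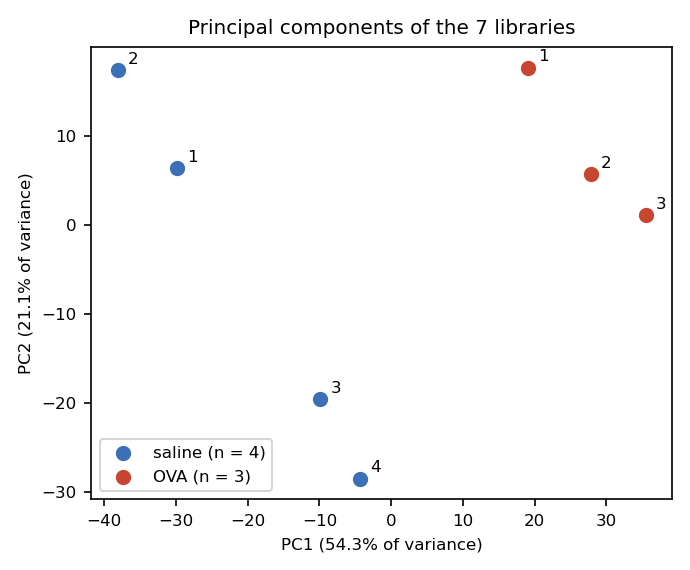
Principal components of the 7 libraries over all genes, PC1 (54.3% of the variance) on the x axis and PC2 (21.1%) on the y axis, with saline in blue and OVA in red and the replicate number beside each point. The OVA libraries lie at 19.1 to 35.5 on PC1 and the saline libraries at -38.2 to -4.39.

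The libraries sorted from OVA lungs held more RNA for Chil3, a secreted chitinase-like protein, Retnla, a secreted product of cells stimulated by type 2 cytokines, Car4, a membrane-bound carbonic anhydrase, and Mmp12, a macrophage elastase. Chil3 and Car4 are also markers of alveolar macrophages, a list with 9 of 20 members higher. Chil3 rose from 6.26 ± 0.39 to 12.47 ± 0.46, a log2 difference of 6.20 (SE 0.25), and Retnla from 7.14 ± 0.32 to 12.38 ± 0.07, a difference of 5.24 (SE 0.16). Car4 rose by 5.36 (SE 0.23) and Mmp12 by 5.18 (SE 0.20), with limma adjusted p of 3.02e-06 and 1.95e-06. Rnase2a, an eosinophil-associated ribonuclease, rose by 4.74, the sodium-calcium exchanger Slc24a3 by 3.98 and the sialomucin Cd34 by 3.86 (SE 0.10, limma adjusted p = 1.38e-07). Enah, Qpct, Lipg, Egr2 and Fbp1 rose by 3.65, 3.57, 3.33, 3.01 and 2.95. The saline levels of Rnase2a (4.32), Qpct (5.36), Lipg (5.39) and Fbp1 (5.45) lay under the negative control median of 5.91, so the size of their rise is uncertain. Each of these 12 genes was higher in 3 of 3 OVA libraries than in any saline library, as the rule that picked them required.

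The largest decrease among called genes was that of Nedd4. The ubiquitin ligase Nedd4 fell by 2.04 (SE 0.20) from 10.42 ± 0.07, with limma adjusted p = 0.00052, and its dimmer second probe set differed by -0.87. The transcription factor Myc fell by 1.76 and the gelatinase Mmp9 by 1.49. Ifitm6, Ston2, St3gal5, Slamf7, the growth factor receptor Met and Clec2i differed by -1.89, -1.53, -1.52, -1.46, -1.44 and -1.35, all past the test. Fut4, Hivep2 and Cmklr1 fell by 1.72, 1.34 and 1.30. Fut4 was not called without OVA 1 (0.0678), OVA 2 (0.0529) or OVA 3 (0.0584). Hivep2 was not called without OVA 1 (0.0652), OVA 2 (0.063), OVA 3 (0.0565) or saline 1 and 2 together (0.0504). Cmklr1 was not called without saline 3 (0.0753), OVA 1 (0.121), OVA 2 (0.121) or OVA 3 (0.152).

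Over all 18187 genes, 960 were higher and 212 lower in OVA by limma at a Benjamini-Hochberg adjusted p under 0.05, so that 81.9% of calls were higher; 320 were higher and 39 lower by at least 2-fold. Of the 1172 called genes, 1168 had no overlap between groups. Among all genes, 11% lay wholly above and 8.61% wholly below the saline range, where chance gives 2.86% for each. The median difference of all genes was -0.07. A second quantile normalization gave 954 higher and 428 lower (69% higher). With saline 1 and 2 left out there were 817 higher and 404 lower, a share of 66.9%, and 854 of these genes were also called with all libraries; at 2-fold 245 were higher and 95 lower. The counts higher and lower were 1649 and 677 with array weights, 2191 and 991 without saline 3 and 4 (also chosen after seeing the data), 102 and 7 by limma's treat against a 1.5-fold change, and 47 and 7 by an unmoderated comparison. The array weights were 5 for OVA replicate 2 and 0.411 to 1.41 for the other libraries. The count lower was 119 after median centring, 411 after cyclic loess and 558 with control separation as a covariate. The counts higher and lower were 580 and 71 without OVA replicate 1, 430 and 67 without OVA replicate 2, and 366 and 86 without OVA replicate 3. Without saline replicate 1 the count lower was 140. At 2-fold, the counts were 591 and 84 without saline 3 and 4, 102 and 7 by treat and 39 and 2 by the unmoderated comparison, and 63, 60 and 102 were lower after quantile normalization again, cyclic loess and with the covariate. At 2-fold, 22 were lower without OVA replicate 1 and 213 higher without OVA replicate 3.

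**Figure D2:**
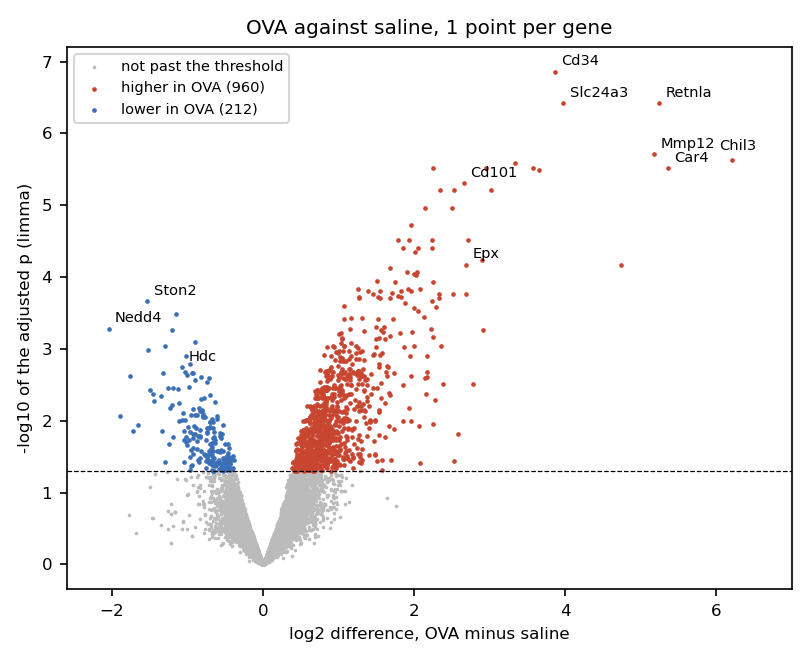
Log2 difference, OVA minus saline (x axis), against the negative log10 of the limma adjusted p (y axis), 1 point per gene, with the dashed line at the threshold. The 960 genes higher in OVA (red) reach a difference of 6.20 at Chil3, and the 212 lower genes (blue) reach -2.04 at Nedd4.

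Of the genes that define eosinophils, 4 were called and the receptors for eotaxin and interleukin-5 were not. Siglecf, the surface lectin used to recognise these cells, rose by 0.83 (SE 0.12) from 9.34 ± 0.16, and the granulocyte transcription factor Cebpe by 0.98. Hdc, which makes histamine, fell by 1.07, and Xbp1, a transcription factor of secretory cells, rose by 1.62. Ccr3, the eotaxin receptor, was 11.97 ± 0.06 in saline and 11.84 ± 0.12 in OVA, Il5ra 9.09 ± 0.41 and 8.73 ± 0.22, Csf2rb 11.33 ± 0.06 and 11.47 ± 0.05, and Alox15 12.24 ± 0.08 and 12.57 ± 0.06 (limma adjusted p = 0.445, 0.357, 0.4 and 0.0915). Il5ra was called lower by limma with saline 1 and 2 left out (-0.70, adjusted p = 0.0334), and its adjusted p ran from 0.00783 to 0.977 over the alternatives. Of 19 measured identity genes 3 were higher and 1 lower, and adjusted over the list alone 4 and 1. The list as a set was not called by camera (adjusted p = 0.144; adjusted p = 0.559 with an estimated correlation).

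Among 10 granule protein genes, the peroxidase Epx rose by 2.69 (SE 0.19) from 6.57 ± 0.09, the major basic protein gene Prg2 by 1.19 (SE 0.15) from 11.83 ± 0.26, and Rnase2a as given above. The ribonuclease genes Ear1, Ear2 and Ear6 fell by 0.62, 0.48 and 0.96. Ear family members share much of their sequence. Ear6 was not called without saline 1 (0.0952), saline 2 (0.0501), saline 3 (0.0832), saline 4 (0.0662), OVA 1 (0.0808), OVA 3 (0.14) or saline 1 and 2 together (0.0719). Ear1 was not called without saline 1 (0.0856), saline 2 (0.0794), saline 3 (0.0831), OVA 1 (0.146), OVA 3 (0.192) or saline 1 and 2 together (0.121). Ear2 was not called without saline 1 (0.0767), saline 2 (0.0597), saline 3 (0.0987), saline 4 (0.0687), OVA 1 (0.157), OVA 3 (0.189) or saline 1 and 2 together (0.0589). Thus 3 genes were higher and 3 lower, and adjusted over the list alone 3 and 6. The median difference was -0.39 and the mean 0.51, and camera gave the downward direction (adjusted p = 0.837; adjusted p = 0.91 with an estimated correlation).

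**Figure D3:**
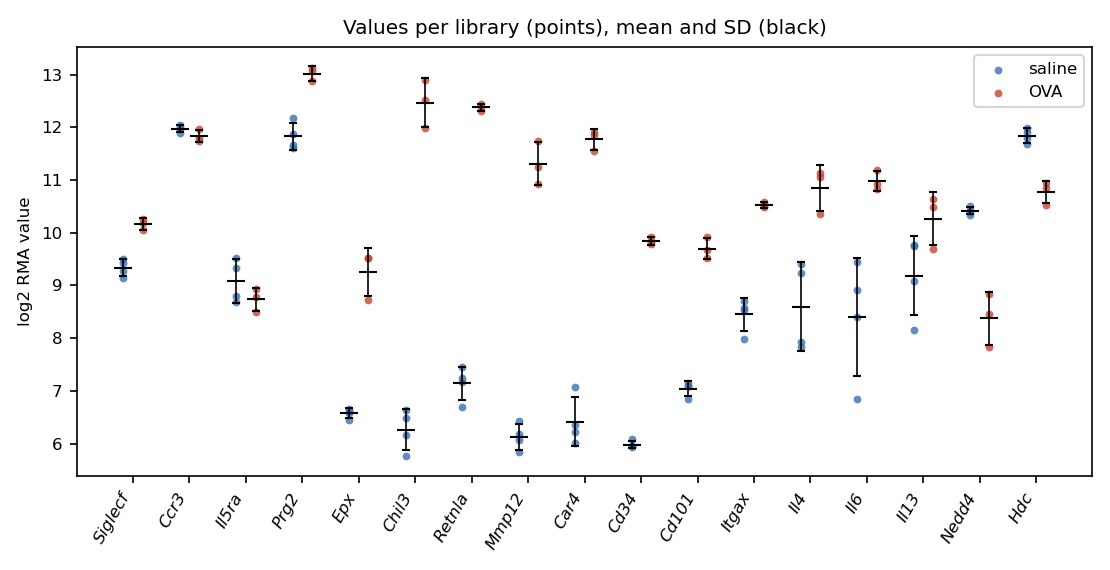
Log2 RMA values per library (y axis) of 17 genes (x axis), saline in blue (n = 4) and OVA in red (n = 3), with the mean and SD in black. Chil3, Retnla, Mmp12 and Cd34 show no overlap between groups, while Ccr3, Il5ra and Il13 overlap.

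Of the genes of type 2 and alternative activation, 11 of 29 rose and 2 fell, and adjusted over the list alone 16 and 2. Beside Chil3, Retnla and Egr2, the mannose receptor Mrc1 rose by 2.07, the arginase Arg1 by 1.67 and the chemokine Ccl24 by 1.42. The saline level of Mrc1, 5.825, lay under the negative control median of 5.91, so the size of its rise is uncertain. Il4ra, the receptor chain for IL-4 and IL-13, rose by 1.02 and Il1rl1, the IL-33 receptor, by 0.58, whereas Myc and Tgm2 fell. The median difference of the type 2 list was 0.56 (camera adjusted p = 1.21e-07; adjusted p = 0.215 with an estimated correlation), and without OVA 1 it was 0.37 (5.12e-06, in a range of 5.19e-09 to 0.215 over the alternatives). Chil3 and Mrc1 are also alveolar macrophage markers, of which 9 of 20 were higher (camera adjusted p = 1.47e-07; adjusted p = 0.259 with an estimated correlation). Mrc1 was not called without OVA 1 (0.0516), OVA 3 (0.0699) or saline 1 and 2 together (0.0608). Arg1 was not called without OVA 3 (0.0777) or saline 1 and 2 together (0.0568). Ccl24 was not called without OVA 3 (0.0531), in a range of 0.00524 to 0.0531 over the alternatives. Il4ra was not called without saline 1 (0.0506), OVA 1 (0.0622), OVA 2 (0.0872), OVA 3 (0.0756) or saline 1 and 2 together (0.0757). Il1rl1 was not called without saline 1 (0.0772), saline 2 (0.0662), saline 3 (0.0648), OVA 1 (0.124), OVA 2 (0.177) or saline 1 and 2 together (0.107). Tgm2 was not called without saline 1 (0.0569), OVA 1 (0.0959), OVA 2 (0.112), OVA 3 (0.0651) or saline 1 and 2 together (0.0575).

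Cytokine genes higher in OVA were Il6 (2.58, SE 0.50), Il4 (2.25, SE 0.40), Mif (1.24), Il1b (1.06), Hbegf (0.73) and Igf1 (0.70), which made 6 of 50 higher and 0 lower, and 8 and 2 adjusted over the list alone. Il13 was 9.19 ± 0.76 in saline and 10.27 ± 0.51 in OVA (limma adjusted p = 0.145). The median difference of the cytokine list was -0.08 and its mean 0.10, with camera upward (adjusted p = 0.628; adjusted p = 0.798 with an estimated correlation). Chemokine genes Cxcl15, Cxcl10, Ccl24 and Ccl20 rose by 2.24, 2.17, 1.42 and 0.49. Thus 4 of 34 chemokines were higher and 0 lower, and 5 and 1 adjusted over the list alone, with a median of -0.04, a mean of 0.14 and camera upward (adjusted p = 0.379; adjusted p = 0.559 with an estimated correlation). Il6 was not called without OVA 1 (0.0602), OVA 2 (0.0762) or OVA 3 (0.0723). Il4 was not called without OVA 1 (0.0557) or OVA 2 (0.0614). Il1b was not called without saline 1 (0.0887), OVA 1 (0.106), OVA 2 (0.124) or OVA 3 (0.143). Hbegf was not called without OVA 2 (0.116), OVA 3 (0.0868) or saline 1 and 2 together (0.0629). Igf1 was not called without OVA 1 (0.0632) or OVA 3 (0.0777). Ccl20 was not called without saline 1 (0.0586), OVA 2 (0.135), OVA 3 (0.119) or saline 1 and 2 together (0.071). The saline level of Cxcl15, 4.43, lay under the negative control median of 5.91, so the size of its rise is uncertain. Ccl24 was not called without OVA 3 (0.0531), in a range of 0.00524 to 0.0531 over the alternatives.

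In the lists of adhesion molecules and of inhibitory and paired receptors, called members were mostly higher. Besides Cd34, the inhibitory receptor Cd101 rose by 2.66 (SE 0.13) from 7.04 ± 0.14, the activation marker Cd69 by 2.36, and the integrin chains Itgae by 2.24 and Itgax, also 1 of the 9 alveolar macrophage markers that were higher, by 2.07 (SE 0.16). In the adhesion list 9 of 28 were higher and 2, among them Vcam1 (-0.74), lower, and 11 and 4 adjusted over the list alone (camera adjusted p = 0.000845; adjusted p = 0.367 with an estimated correlation). Camera on ranks did not call it (adjusted p = 0.246, in a range of 0.000313 to 0.367 over the alternatives). Vcam1 was not called without OVA 1 (0.0643) or OVA 2 (0.0782). Inhibitory and paired receptors had 6 of 29 higher, among them Trem1 (1.85), Clec4a3 (1.51) and Siglecg (1.05), and 0 lower, and 7 and 3 adjusted over the list alone (camera adjusted p = 0.178; adjusted p = 0.559 with an estimated correlation), and the list was called higher without saline 3 and 4 together (0.0451, in a range of 0.0451 to 0.897). Clec4a3 was not called without saline 3 (0.0735), OVA 1 (0.134), OVA 2 (0.0507) or OVA 3 (0.175).

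Receptors for antibody and complement were higher where called. Itgax, also an alveolar macrophage marker, the complement gene C3 (1.30), Fcgr2b (0.80), Fcgr1 (0.64) and Fcgr3 (0.53) were the 5 of 20 Fc and complement genes that rose, with 0 lower, and 5 and 0 adjusted over the list alone (camera adjusted p = 0.00967; adjusted p = 0.358 with an estimated correlation). With saline 1 and 2 left out the camera adjusted p was 0.181 and with control separation as a covariate 0.214, and over the alternatives it ran from 0.00379 to 0.358. Tlr4, Tlr2 and Il1rl1 rose by 1.37, 1.04 and 0.58, Tlr6 and Nod1 fell by 1.02 and 0.50, and 3 of 28 pattern recognition genes were higher and 2 lower, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.592; adjusted p = 0.812 with an estimated correlation), and that list was called higher without saline 3 and 4 together (0.0451, in a range of 0.0451 to 0.916). Among 31 chemoattractant receptors 3 were higher, with Ccrl2 at 0.73 and Fpr2 at 0.50, and 1, the nucleotide receptor P2ry2, lower (-0.99), and 4 and 1 adjusted over the list alone (camera adjusted p = 0.228; adjusted p = 0.367 with an estimated correlation). Fcgr1 was not called without saline 1 (0.0767), saline 2 (0.0521), OVA 1 (0.0626), OVA 2 (0.146), OVA 3 (0.093) or saline 1 and 2 together (0.102). Fcgr3 was not called without OVA 2 (0.1) or OVA 3 (0.093). Tlr2 was not called without OVA 2 (0.0581) or OVA 3 (0.0601). Tlr6 was not called without saline 1 (0.0527), OVA 1 (0.0697) or OVA 3 (0.0608). Nod1 was not called without saline 1 (0.101), saline 2 (0.0854), saline 3 (0.0958), OVA 1 (0.16), OVA 2 (0.193) or saline 1 and 2 together (0.133). Il1rl1 was not called without saline 1 (0.0772), saline 2 (0.0662), saline 3 (0.0648), OVA 1 (0.124), OVA 2 (0.177) or saline 1 and 2 together (0.107). Fpr2 was not called without saline 1 (0.0937), saline 2 (0.0761), OVA 1 (0.132), OVA 2 (0.126), OVA 3 (0.161) or saline 1 and 2 together (0.103). P2ry2 was not called without OVA 1 (0.0816), OVA 2 (0.0529) or OVA 3 (0.0834).

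In the list of the unfolded protein response, which concerns protein folding in the endoplasmic reticulum, and that of hypoxia and glycolysis, 11 of 27 and 14 of 30 genes rose. Xbp1 rose by 1.62 (SE 0.17), the chaperone gene Dnajb9 from 8.55 ± 0.14 to 10.05 ± 0.10, and the disulfide isomerases Pdia6 and Pdia4 by 1.16 and 1.00. In the unfolded protein response list 11 of 27 were higher and 0 lower, and 16 and 0 adjusted over the list alone, with a median of 0.51 (camera adjusted p = 1.49e-12; adjusted p = 0.256 with an estimated correlation). The oxygen sensor Egln3 rose by 2.38, P4ha1 by 1.61, hexokinase Hk2 by 1.55 and Ero1a by 1.34, and 14 of 30 hypoxia and glycolysis genes were higher and 0 lower, and 19 and 2 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 2.17e-11; adjusted p = 0.256 with an estimated correlation). P4ha1 was not called without OVA 1 (0.0768), OVA 2 (0.065) or OVA 3 (0.0699).

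Respiratory chain genes Ndufa5, Ndufs3 and Cyc1 rose by 0.78, 0.76 and 0.69, which were the 3 of 40 oxidative phosphorylation genes called, with 0 lower and 3 and 0 adjusted over the list alone (camera adjusted p = 4.95e-05; adjusted p = 0.559 with an estimated correlation). With saline 1 and 2 left out the camera adjusted p was 0.454 and with control separation as a covariate 0.35, and by fry 0.25, in a range over the alternatives of 3.26e-09 to 0.559. The mean level of the list was 9.47, 9.35, 9.79 and 9.86 in saline 1 to 4. Of 49 ribosomal protein genes only Rpl3 was called, higher by 0.56, both over all genes and adjusted over the list alone (camera adjusted p = 0.638, downward; adjusted p = 0.912 with an estimated correlation), and camera called the list lower without OVA 3 (0.0286), without saline 1 and 2 together (0.00561) after cyclic loess (0.022) and with the covariate (0.000326), in a range of 0.000326 to 0.935. In cell cycle genes, Rrm1 (1.07), Mcm4 (0.69), Tyms (0.60) and Top2a (0.59) were the 4 of 39 higher, with 0 lower, and 8 and 0 adjusted over the list alone (camera adjusted p = 0.0347; adjusted p = 0.358 with an estimated correlation). Camera did not call the cell cycle list without saline 1 (0.0737), saline 4 (0.0734), OVA 1 (0.0999), saline 1 and 2 together (0.056) or saline 3 and 4 together (0.0989). Nor was it called with the replicate block (0.0698), dim genes left out (0.105), array weights (0.151) or by fry (0.057), and over the alternatives its adjusted p ran from 0.00242 to 0.358. Ndufa5 was not called without OVA 3 (0.0586), in a range of 0.00207 to 0.0586 over the alternatives. Ndufs3 was not called without saline 1 (0.103), saline 2 (0.0883), saline 3 (0.0947), OVA 2 (0.14), OVA 3 (0.196) or saline 1 and 2 together (0.154). Cyc1 was not called without saline 1 (0.0852), saline 2 (0.0502), OVA 1 (0.0769), OVA 2 (0.146), OVA 3 (0.141) or saline 1 and 2 together (0.059). Rpl3 was not called without OVA 3 (0.0571), in a range of 0.00341 to 0.0571 over the alternatives. Top2a was not called with the mean of all its probe sets (0.132), in a range of 0.00115 to 0.132. Rrm1 was not called without saline 1 (0.0616), OVA 2 (0.0977) or OVA 3 (0.114). Mcm4 was not called without saline 1 (0.0875), saline 2 (0.059), OVA 1 (0.07), OVA 2 (0.116), OVA 3 (0.168) or saline 1 and 2 together (0.0939). Tyms was not called without saline 1 (0.0942), saline 2 (0.087), saline 3 (0.0988), OVA 1 (0.156), OVA 2 (0.0636), OVA 3 (0.208) or saline 1 and 2 together (0.135).

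Among targets of the inflammatory regulator NF-kappaB, Tnfaip2 rose by 2.17, the adhesion molecule Icam1 by 1.36, the prostaglandin synthase Ptgs2 by 1.13 and the inhibitor gene Nfkbia by 1.11. In this list 12 of 30 rose and 0 fell, and 15 and 0 adjusted over the list alone (camera adjusted p = 3.94e-08; adjusted p = 0.367 with an estimated correlation). The mean level of the list was 9.60 ± 0.34 in saline and 10.06 ± 0.07 in OVA, with 9.45 and 9.21 in saline 1 and 2, and fry did not call it (adjusted p = 0.084, in a range of 1.76e-11 to 0.367 over the alternatives). Immediate early genes, which also respond to tissue dissociation, had 7 of 32 higher, with Egr2, Jun (1.98), Atf3 (0.77) and Egr1 (0.74) at the top, and 1, Dusp5, lower, and 8 and 1 adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.362 with an estimated correlation). Icam1 was not called without OVA 3 (0.0708), in a range of 0.000645 to 0.0708 over the alternatives. Egr1 was not called without OVA 2 (0.0674), in a range of 0.00136 to 0.0674 over the alternatives. Dusp5 was not called without OVA 2 (0.0707) or OVA 3 (0.0611). The immediate early list was not called by camera after cyclic loess (0.0592), in a range of 3e-04 to 0.362 over the alternatives.

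Ptgs1 and Ptgs2, both prostaglandin synthases, rose by 1.54 and 1.13, Pla2g4a, which frees arachidonic acid, by 0.88 and the lipoxygenase Alox5 by 0.65, so that 4 of 30 eicosanoid genes were higher and 0 lower, and 5 and 0 adjusted over the list alone (camera adjusted p = 0.0115; adjusted p = 0.259 with an estimated correlation). The survival genes Bcl2l1, Pim2, Bcl2, Cflar and Birc3 rose by 1.75, 1.33, 0.89, 0.88 and 0.77, and the pro-apoptotic genes Bcl2l11 and Pmaip1 fell by 0.53 and 0.74. In that list 5 of 32 were higher and 2 lower, and 10 and 2 adjusted over the list alone (camera adjusted p = 0.0118; adjusted p = 0.383 with an estimated correlation). Camera did not call the survival list without saline 2 (0.0554) or saline 1 and 2 together (0.318), after cyclic loess (0.0933), with dim genes left out (0.105) or with the covariate of control separation (0.284), nor did fry (0.0888). The eicosanoid list was not called without saline 1 and 2 together (0.0777) or with dim genes left out (0.105), and over the alternatives the adjusted p of the survival and eicosanoid lists ran from 0.00103 to 0.383 and from 0.0039 to 0.259. Alox5 was not called without saline 1 (0.0917), OVA 1 (0.0746), OVA 2 (0.151), OVA 3 (0.173) or saline 1 and 2 together (0.0646). Bcl2 was not called without OVA 1 (0.0637), OVA 2 (0.0941) or OVA 3 (0.0688). Cflar was not called without OVA 1 (0.0725), OVA 2 (0.0685) or OVA 3 (0.0559). Birc3 was not called without OVA 2 (0.0644) or OVA 3 (0.0546). Bcl2l11 was not called without saline 1 (0.104), saline 2 (0.0773), saline 3 (0.0839), saline 4 (0.0638), OVA 1 (0.153), OVA 2 (0.186) or saline 1 and 2 together (0.121).

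Interferon response genes went the other way in part. Ifitm3, Irf7, Oasl1 and Xaf1 fell by 1.15, 0.89, 0.66 and 0.53, while Cxcl10 rose by 2.17, so that 1 of 32 was higher and 4 lower, and 1 and 6 adjusted over the list alone. The list was not called (camera adjusted p = 0.0791, downward; adjusted p = 0.559 with an estimated correlation). It was called lower without saline 1 (camera adjusted p = 0.0272), saline 2 (0.018), OVA 1 (0.0487), OVA 3 (0.0447) or saline 1 and 2 together (0.00168), after cyclic loess (0.0464), with dim genes left out (0.00911), with array weights (0.0142) and with control separation as a covariate (0.012), in a range of 0.00168 to 0.601 over the alternatives. Irf7 was not called without OVA 1 (0.0667), OVA 2 (0.0795) or OVA 3 (0.0506). Oasl1 was not called without OVA 1 (0.0511), OVA 2 (0.0794) or OVA 3 (0.0689). Xaf1 was not called without saline 1 (0.0581), OVA 1 (0.0847), OVA 2 (0.129) or OVA 3 (0.0893).

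Of antigen presentation genes for MHC class II, the protease gene Ctss rose by 2.78, the costimulatory ligand Icosl by 1.25 and Cd274, which encodes PD-L1, by 0.53, giving 3 of 19 higher and 0 lower, and 3 and 0 adjusted over the list alone. The class II molecules themselves were not among the calls. Camera called the list (adjusted p = 0.0424; adjusted p = 0.358 with an estimated correlation), and the call was lost without saline replicate 1 (0.0555), saline replicate 2 (0.0558), saline replicate 4 (0.0599), OVA replicate 1 (0.078), OVA replicate 3 (0.0917), saline 1 and 2 together (0.126) or saline 3 and 4 together (0.0779). Nor was it called with the replicate block (0.0628), quantile normalization again (0.067), cyclic loess (0.0933), dim genes left out (0.232), array weights (0.235), the covariate (0.108), camera on ranks (0.128) or fry (0.0538), in a range of 0.00791 to 0.358 over the alternatives. The chaperones Calr (0.81) and Canx (0.51) were the 2 of 17 MHC class I genes higher, with 0 lower and 2 and 0 adjusted over the list alone (camera adjusted p = 0.155; adjusted p = 0.716 with an estimated correlation). MHC class I genes were called as a list without saline 4 (camera adjusted p = 0.0458), without saline 3 and 4 together (0.0102) and with the replicate block (0.0492), in a range of 0.0102 to 0.827 over the alternatives. Cd274 was not called without saline 1 (0.0727), saline 3 (0.099), saline 4 (0.0706), OVA 1 (0.0647), OVA 2 (0.161) or OVA 3 (0.22). Calr was not called without OVA 2 (0.0666) or OVA 3 (0.0704). Canx was not called without saline 1 (0.0746), saline 2 (0.0649), OVA 1 (0.112), OVA 2 (0.163), OVA 3 (0.0945) or saline 1 and 2 together (0.0895).

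The cathepsin genes Ctsk, Ctss and Ctsc rose by 2.92, 2.78 and 1.26 and the superoxide dismutase Sod2 by 1.09, among 8 of 26 oxidase and protease genes higher and 0 lower, and 11 and 2 adjusted over the list alone (camera adjusted p = 0.00548; adjusted p = 0.367 with an estimated correlation). The fatty acid transporter Cd36 rose by 2.72 (SE 0.17) from 4.29 ± 0.14, the triglyceride enzyme Dgat2 by 1.96, the nuclear receptor Pparg by 1.54 and lipoprotein lipase Lpl by 1.48. That saline level of Cd36 lay under the negative control median of 5.91, so the size of its rise is uncertain. In lipid handling 11 of 34 were higher and 1, the exporter Abca1, lower, and 17 and 4 adjusted over the list alone (camera adjusted p = 3.68e-06; adjusted p = 0.256 with an estimated correlation). Ctsk, Pparg and Lpl are also alveolar macrophage markers, of which 9 of 20 were higher (camera adjusted p = 1.47e-07; adjusted p = 0.259 with an estimated correlation). Besides Mmp12 and Mmp9, Fn1 rose by 2.33 and Mmp19 by 1.11. Tissue remodelling had 9 of 34 higher and 2 lower, the other being the protease Adam8 (-0.61), and 11 and 3 adjusted over the list alone, with a median of -0.11, a mean of 0.28 and camera upward (adjusted p = 0.138; adjusted p = 0.367 with an estimated correlation), and fry called the list higher (adjusted p = 0.0161, in a range of 0.0161 to 0.642 over the alternatives). The oxidase and protease list was not called without saline 1 and 2 together (0.115), with control separation as a covariate (0.103), by camera on ranks (0.132) or by fry (0.0538), and the range over the alternatives was 0.000494 to 0.367. Sod2 was not called without saline 1 (0.0677), OVA 1 (0.0673), OVA 2 (0.0864) or OVA 3 (0.128). Mmp19 was not called without OVA 3 (0.0611), in a range of 0.00418 to 0.0611 over the alternatives. Abca1 was not called without saline 1 (0.0729), saline 2 (0.0548), OVA 2 (0.134), OVA 3 (0.142) or saline 1 and 2 together (0.0918).

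A list of 6 genes described in earlier work as high in lung-resident eosinophils was lower in OVA. Of these, 2 fell, among them Nedd4, the other 4 were not called, and adjusted over the list alone there were 0 higher and 2 lower, with a median of -0.61 (camera adjusted p = 0.0267; adjusted p = 0.358 with an estimated correlation). Serpinb1a was 7.53 in saline and 6.52 in OVA (limma adjusted p = 0.324). The list was not called without saline 3 (camera adjusted p = 0.065), saline 4 (0.0839; median -0.35), saline 3 and 4 together (0.433), with the replicate block (0.0946) or with camera on ranks (0.128), in a range of 0.000212 to 0.433 over the alternatives.

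**Figure D4:**
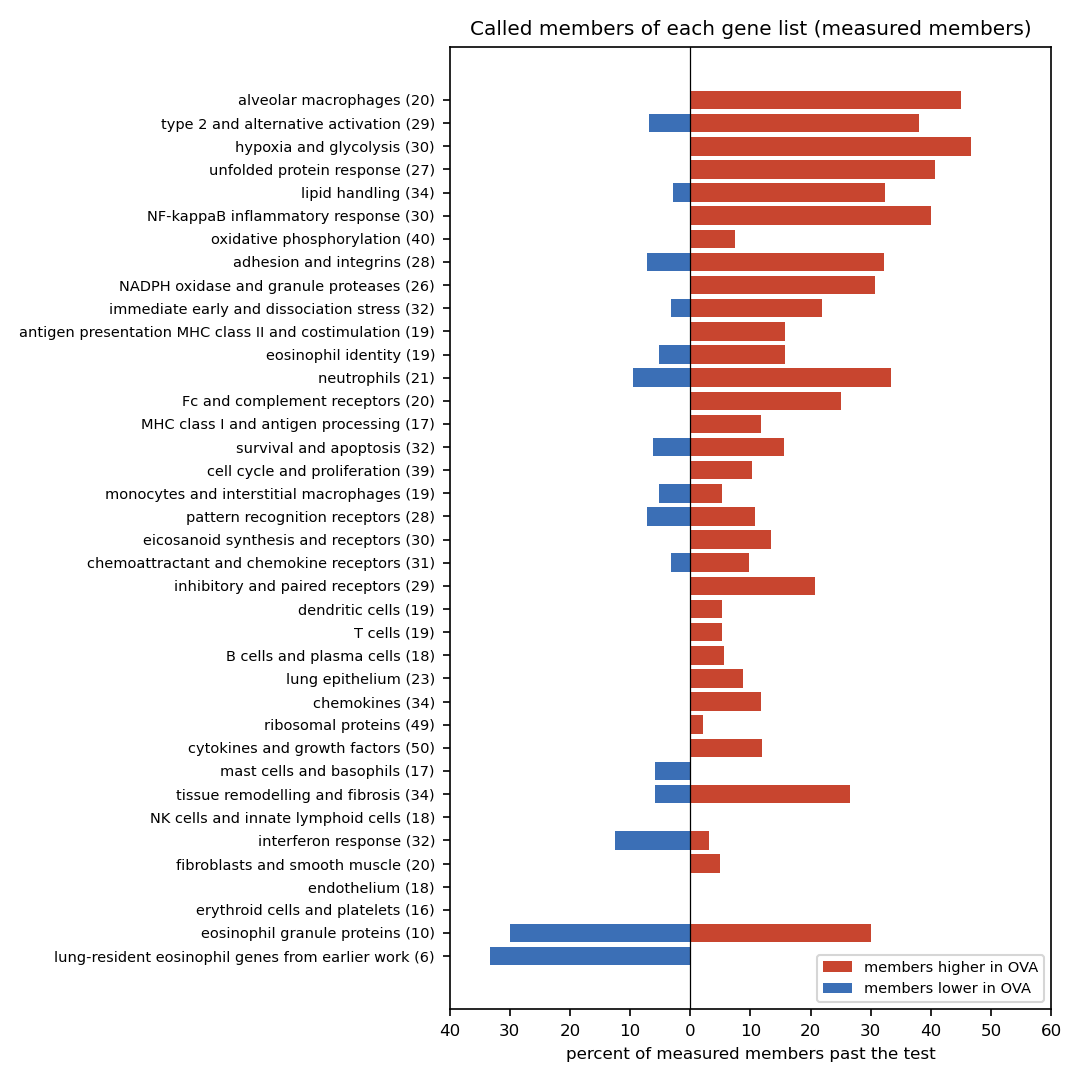
Percent of the measured members of each gene list past the test (x axis), with members higher in OVA in red to the right and lower in blue to the left; the number measured stands in brackets and lists are ordered by their median difference. Hypoxia and glycolysis has 14 of 30 members higher, and endothelium and NK cells have 0 called.

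Markers of alveolar macrophages, cells of the same airspaces, were higher in part. Of 20 measured, 9 were higher and 0 lower, and 12 and 1 adjusted over the list alone: Chil3, Car4, Ctsk, Atp6v0d2 (2.27), Itgax, Mrc1, Pparg, Lpl and Cd2. The other 11 were not called, among them Marco (-0.19, SE 0.14), Fabp4 (0.42, SE 0.15), Siglec1 (-0.24) and Cidec (-0.30). The saline levels of Atp6v0d2 (4.985) and Mrc1 (5.825) lay under the negative control median of 5.91, so the size of their rise is uncertain. The list was higher by camera (adjusted p = 1.47e-07; adjusted p = 0.259 with an estimated correlation), with a mean level of 6.22 ± 0.12 in saline and 7.47 ± 0.26 in OVA. Of the 9 called markers 7 also stand in another list: Chil3 and Mrc1 in type 2 activation, Pparg and Lpl in lipid handling, Ctsk in oxidase and proteases, Itgax in adhesion and Cd2 in T cells. Mrc1 was not called without OVA 1 (0.0516), OVA 3 (0.0699) or saline 1 and 2 together (0.0608). Cd2 was not called without saline 1 (0.0723), OVA 1 (0.107), OVA 3 (0.142) or saline 1 and 2 together (0.0945).

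**Figure D5:**
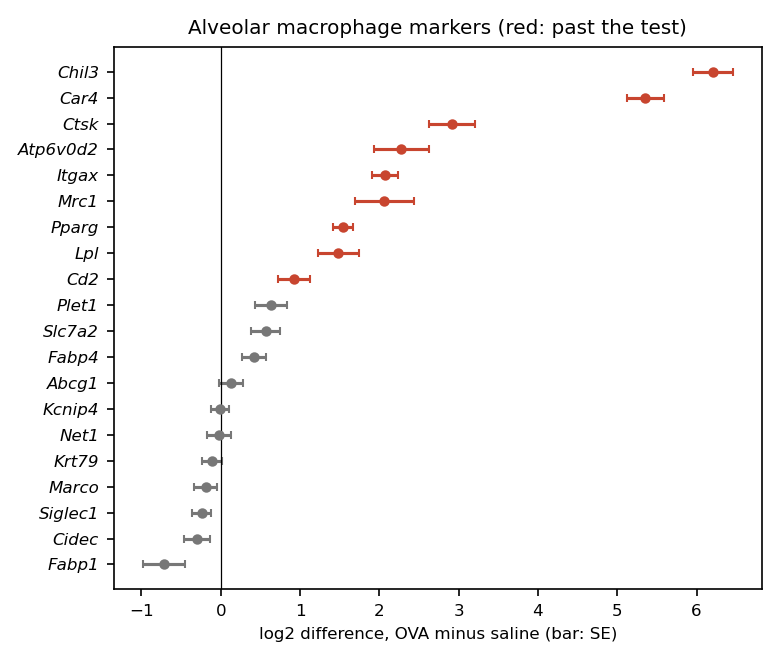
Log2 difference, OVA minus saline, with its SE (x axis) for the 20 alveolar macrophage markers (y axis), those past the test in red. Chil3 and Car4 lie above 5, while Marco, Siglec1 and Cidec lie below 0.

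Surfactant genes were the called markers of lung epithelium. In lung epithelium, Sftpc rose by 2.53 (SE 0.59) from 8.14 ± 1.26 to 10.67 ± 0.63 and Sftpa1 by 0.52, the 2 of 23 called, with 0 lower and 2 and 0 adjusted over the list alone; the median was -0.03, the mean 0.14 and camera upward (adjusted p = 0.446; adjusted p = 0.76 with an estimated correlation). In neutrophil markers 7 of 21 were higher, among them Cstdc5 (2.16), Trem1 (1.85), Stfa2 (1.40) and Ngp (1.34), and Mmp9 and Hdc lower, and 9 and 4 adjusted over the list alone (camera adjusted p = 0.0844; adjusted p = 0.358 with an estimated correlation). S100a8 and S100a9 were 8.54 and 10.53 in saline and differed by -0.19 and 0.61 (limma adjusted p = 0.89 and 0.448). Neutrophil markers were called as a list without OVA 1 (camera adjusted p = 0.041), in a range of 0.041 to 0.358 over the alternatives. Sftpc was not called without saline 1 (0.101), saline 2 (0.059), saline 4 (0.0502), OVA 1 (0.0927), OVA 2 (0.161), OVA 3 (0.109) or saline 1 and 2 together (0.118). Sftpa1 was not called without saline 1 (0.0565), OVA 1 (0.0684), OVA 2 (0.129), OVA 3 (0.114) or saline 1 and 2 together (0.0554). Stfa2 was not called without saline 1 (0.0789), saline 2 (0.0597), OVA 2 (0.13), OVA 3 (0.132) or saline 1 and 2 together (0.122). Its second probe set differed by only 0.21. The Stfa2 levels, 4.15 in saline and 5.55 in OVA, lay under the negative control medians of 5.91 and 6.09, so its rise is uncertain.

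Erythroid and platelet genes were lower as a set although 0 of 16 passed the test over all genes; adjusted over the list alone, 0 were higher and 5 lower. Hba-a2 and Hba-a1, both alpha globins, were 12.01 ± 0.38 and 11.94 ± 0.39 in saline and 11.01 ± 0.74 and 10.94 ± 0.71 in OVA (limma adjusted p = 0.109 and 0.105), and the list's median difference was -0.29 (camera adjusted p = 0.0118; adjusted p = 0.256 with an estimated correlation). Without OVA 3 that median was -0.18 (0.01, in a range of 0.0014 to 0.256 over the alternatives). For monocytes and interstitial macrophages Fcgr1 was higher and Maf lower (-0.53) of 19, with 1 and 1 adjusted over the list alone (camera adjusted p = 0.68; adjusted p = 0.76 with an estimated correlation). Dendritic cell markers had Itgae alone higher of 19, and 2 and 0 adjusted over the list alone, with a median of -0.002, a mean of 0.15 and camera upward (adjusted p = 0.615; adjusted p = 0.798 with an estimated correlation). Mast cell and basophil markers had Hdc alone lower of 17, the same count adjusted over the list alone (camera adjusted p = 0.238; adjusted p = 0.559 with an estimated correlation). Maf was not called without OVA 1 (0.0516), OVA 2 (0.0533) or OVA 3 (0.0584). Fcgr1 was not called without saline 1 (0.0767), saline 2 (0.0521), OVA 1 (0.0626), OVA 2 (0.146), OVA 3 (0.093) or saline 1 and 2 together (0.102).

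Cd2 rose by 0.92, the 1 of 19 T cell markers higher, with 0 lower and 1 and 1 adjusted over the list alone (camera adjusted p = 0.757; adjusted p = 0.883 with an estimated correlation). Jchain rose by 1.30, the 1 of 18 B and plasma cell markers called, with 1 and 0 adjusted over the list alone, a median of -0.01, a mean of 0.01 and camera downward (adjusted p = 0.717; adjusted p = 0.817 with an estimated correlation). Fn1 was the 1 of 20 fibroblast and smooth muscle markers higher, over all genes and adjusted over the list alone (camera adjusted p = 0.266; adjusted p = 0.76 with an estimated correlation). By limma 0 of 18 NK and innate lymphoid markers and 0 of 18 endothelial markers were called, and 0 adjusted over the list alone (camera adjusted p = 0.446 and 0.0844; adjusted p = 0.612 and 0.608 with an estimated correlation). Il17rb and Klrk1 differed by 0.31 and -0.30, and Pecam1 and Ramp2 by 0.60 and -0.31 (limma adjusted p = 0.18, 0.237, 0.0989 and 0.203). Pecam1 was called higher without saline 3 (0.72, limma adjusted p = 0.048), in a range of 0.00557 to 0.375 over the alternatives. Endothelial markers were called lower as a list without saline 4 (camera adjusted p = 0.0458) or OVA 1 (0.0415), with the replicate block (0.0492) or with camera on ranks (0.0449), in a range of 0.0415 to 0.608 over the alternatives. Cd2 was not called without saline 1 (0.0723), OVA 1 (0.107), OVA 3 (0.142) or saline 1 and 2 together (0.0945). Jchain differed by 0.85 without OVA 3. Its saline level, 4.995, lay under the negative control median of 5.91, so the size of its rise is uncertain. Jchain was not called without saline 1 (0.103), saline 3 (0.0789), OVA 1 (0.0637), OVA 3 (0.0522) or saline 1 and 2 together (0.0969).

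In all, camera called 15 of the 38 lists higher and 2 lower at its preset correlation, and 0 with an estimated one, where the lowest adjusted p was 0.215 and 7 lists had an unadjusted p under 0.05. The mean level per library gave the smallest exact permutation p of 0.02857 for 16 lists, which is 0.0679 after Benjamini-Hochberg adjustment over the 38 lists, so no list passed by that test. With saline 1 and 2 left out camera called 8 lists higher and 4 lower; with all libraries fry called 10 and 2. The lower lists numbered 4 without OVA replicate 1, 4 without OVA replicate 3, 1 without saline replicate 3, 1 without saline 3 and 4 together, 4 after cyclic loess and 4 with control separation as a covariate.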

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

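The test for alveolar macrophage RNA, the analyses without saline replicates 1 and 2, without saline replicates 3 and 4 and with control separation as a covariate, and the count of markers with a narrow interval were chosen after values were seen; the other tests were not. Among 164 results (126 named genes and 38 list levels), the lowest or highest of the 4 saline libraries stood far from the other 3 in 7, where chance gives about 1 in 20, or 8.2.

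Saline replicate 1 stood apart in Rnase2a (4.6 against 4.2 to 4.26), Oasl1 (8.86 against 8.46 to 8.48) and the level of the hypoxia and glycolysis list (9.54 against 9.24 to 9.26). Saline replicate 3 did so in Mrc1 (6.75 against 5.44 to 5.64) and in the level of erythroid and platelet genes (7.65 against 7.46 to 7.48). Saline replicate 4 did so in Slamf7 (7.44 against 8.20 to 8.34) and Siglecg (8.79 against 8.24 to 8.25). Outside the named genes, 159 of 9241 probe sets with no gene symbol were higher in OVA and 42 were lower by limma when every probe set was tested.

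The counts of genes can be set against the other groupings of the libraries. Of the 35 splits, 1, the real one, gave as many genes higher (960, highest other 1) and 1 gave as many lower (212, highest other 30). By 2-fold, 1 gave as many higher (320, highest other 1) and 1 as many lower (39, highest other 20). For these counts the real split stood first, at the smallest exact permutation p that 35 splits allow, 0.02857. Splits that mix the groups hold the group difference within their spread, and so tend to call few genes. Chance is argued against for these counts but not excluded. A difference between arrays that follows the groups is not tested by the splits. For gene lists higher, 2 of 35 splits gave 15 or more (highest other 18), and for lists lower 23 of 35 gave 2 or more (highest other 15), so chance is not excluded for the counts of lists. The 18 came from saline replicate 4 with OVA replicates 1 and 3, and the 15 from splits that set saline replicates 1 and 2 with another saline library.

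Markers of alveolar macrophages were higher in OVA, with 9 of 20 called and, among the 16 at or under 7 log2 in saline, differences from -0.71 for Fabp1 to 6.20 for Chil3. Weaker array signal in saline replicates 1 and 2 is argued against, though weakly. Against saline replicates 3 and 4 alone, the median difference of the called markers was 0.948 of that with all libraries. The median of the ratios per marker had a 95% bootstrap interval of 0.821 to 1.06. Both fits share the OVA libraries and saline replicates 3 and 4, and the markers were picked as called with all libraries. The bootstrap intervals in this paragraph resample markers as if independent, and leave out the spread between libraries. RNA from alveolar macrophages in the OVA sort stays open: those 16 had a median difference of 0.744, with a 95% bootstrap interval of -0.0208 to 2.07, which meets neither the bound set for it nor the bound set against it. In 8 of these 16, among them Marco, Fabp4 and Siglec1 (5.91, 5.67 and 6.44 in OVA), the 95% interval lay under a difference of 1, a count that was picked after the values were seen and decides nothing. A change of the eosinophils after allergen challenge, which the design names, may also account for the rise, and 9 of the 20 markers stand in another list. The design text states a sort with high purity, but the values used here do not show whether macrophages were removed. The mean level of the list was 7.758, 7.253 and 7.404 in OVA replicates 1, 2 and 3. Mmp12, Ctss, C3 and Cd36, which are not in the list, had the same order, as did the members Ctsk, Mrc1 and Atp6v0d2. The members Car4 and Pparg did not, nor did Retnla, Fn1 and Cd34. These genes were picked after values were seen, and a shared source was not tested.

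Of the lung epithelium markers, Sftpc and Sftpa1 were higher in OVA. Epithelial RNA carried into the OVA sort, as the source of a shared rise, is argued against weakly and only for the transcripts tested. Sftpa1, Sftpb, Sftpd, Slc34a2, Lamp3 and Napsa had a median difference of 0.122 (95% bootstrap interval -0.0354 to 0.36), which met the bound set against it. That interval resamples the transcripts as if independent, and leaves out the spread between libraries. The saline levels of these transcripts were 7.16, 7.16, 6.44, 5.48, 4.62 and 8.38. Slc34a2 and Lamp3 thus lay under the negative control median of 5.91 in saline and could hardly show a small amount. The test left out Sftpc, so an amount of free RNA that shows only in Sftpc or a few other transcripts is not ruled out. Whether weaker array signal in saline replicates 1 and 2 accounts for it cannot be told apart with 2 called markers, whose difference against saline replicates 3 and 4 was 0.725 of that with all libraries.

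More genes were higher than lower in OVA, 960 against 212, or 81.9% of calls. The share was 66.9% (817 and 404; 95% exact binomial interval 64.2 to 69.5) without saline replicates 1 and 2, 68.9% (2191 and 991) without saline replicates 3 and 4, 60.9% (58.3 to 63.5) with control separation as a covariate and 73.4% (1137 and 411; 71.2 to 75.6) after cyclic loess, with intervals that treat genes as independent, which they are not. Array signal of saline replicates 1 and 2 cannot be told apart from a difference between the challenges: their removal left the share above the bound of 60% set beforehand, but that of the other pair lowered it too, and the covariate's interval reaches the bound. The deposited normalization stays open as well, since cyclic loess ran on values already normalised and cannot undo that step. A difference between the challenges, which the design names, was not tested apart from the groups. The median of the negative control probe sets also parted the groups, at 5.91 in saline and 6.09 in OVA, and its part in the share was not tested.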

How the results depend on the processing

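The analyses without saline replicates 1 and 2, without saline replicates 3 and 4 and with control separation as a covariate were chosen after the data were seen. Of 126 named genes 115 were called. All 115 kept their direction in the 18 alternatives that gave gene values, and 67 of them kept their call in each. Among results called by the main test or by the alternative, 0 reversed. Some uncalled results changed sign, 3 of them with array weights. The granule protein list was downward by camera and upward by fry (fry adjusted p = 0.0943). The cause was not tested unless given. Genes lower numbered 428 after quantile normalization again, 411 after cyclic loess and 119 after median centring, and lower by 2-fold 63 and 60 after the first and second; cyclic loess called 4 lists lower. Array weights, which gave OVA replicate 2 a weight of 5 and the other libraries 0.411 to 1.41, called 1649 higher and 677 lower. Without saline replicates 1 and 2 there were 404 lower, 95 lower by 2-fold, 8 lists higher and 4 lower; without saline replicates 3 and 4, 2191 higher, 991 lower, 591 and 84 by 2-fold and 1 list lower; with control separation as a covariate, 558 lower, 102 lower by 2-fold and 4 lists lower. Camera with an estimated correlation called 0 lists higher and 0 lower (7 at an unadjusted p under 0.05), against 10 and 2 by fry and 12 and 2 by camera on ranks. Tested against a 1.5-fold change, 102 were higher and 7 lower, all by 2-fold, as the construction is stricter; an unmoderated comparison with unequal variances called 47 and 7, of which 39 and 2 by 2-fold, with 3016 genes at an unadjusted p under 0.05. Leaving out 1 library gave 366 to 1219 higher, 67 to 266 lower, 213 to 382 and 22 to 55 by 2-fold, 13 to 15 lists higher and 1 to 4 lower. The replicate block gave 1361 higher and 318 lower; deviations of libraries with the same number correlated at 0.273, -0.137 and 0.241, and no OVA library correlated best with the saline library of its own number, so the numbers were not taken as pairs. Among other results, 222 gene calls and 66 list calls were lost and 13 and 24 gained over all alternatives. Signal over background limits dim genes: with those under 5.97 log2 left out, 991 were higher and 227 lower. The other deposited table, correction of scanner intensities and a block by scan date were not run.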

Other observations

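The terms of the deposited annotation were tested after the data were seen, and the genes named here were chosen after their values were seen. Of the nucleosome assembly term, which holds histone genes and others such as Tspyl2 (0.94) and Set (0.56), 22 of 74 genes rose and 1, Cenpa, fell. H2bc21 rose by 1.95 (SE 0.34), H4c4 by 1.68 (SE 0.25), H2bc8 by 1.33 (SE 0.13) and the histone chaperone Asf1a by 1.28 (SE 0.17), with limma adjusted p of 0.0102, 0.00445, 0.000557 and 0.00226. Histone genes are near-identical copies, so single members are uncertain. In DNA replication 16 of 96 rose and 0 fell, with Rpa3 (1.21), Pold3 (1.04) and Lig1 (0.85), and in chromosome segregation 8 of 26 rose and 0 fell, with Nek6 (1.27) and Dsn1 (1.15). Camera gave these terms adjusted p of 6.49e-08, 5.84e-07 and 2.15e-05, and adjusted p = 0.749, 0.674 and 0.674 with an estimated correlation. Without saline replicates 1 and 2 the camera adjusted p was 0.000108, 0.000108 and 0.000962.

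Among enzymes of sterol synthesis, Idi1 rose by 2.14 (SE 0.29), Fdft1 by 1.40, Hmgcs1 by 1.30 and Msmo1 by 1.17, and they were among 7 of 21 genes of the term that rose and 0 that fell (camera adjusted p = 0.00466; adjusted p = 0.749 with an estimated correlation). Without saline replicates 1 and 2 the camera adjusted p was 0.123. Over all 308 terms camera called 39 higher and 11 lower, 14 and 0 without saline replicates 1 and 2, and 0 with an estimated correlation, where 16 had an unadjusted p under 0.05. Of the lower terms, response to pheromone and neurotransmitter transport had 0 of 97 and 0 of 38 genes called, with medians of -0.127 and -0.138. Cell-cell adhesion had 4 of 42 lower and 1 higher. The terms were not tested with dim genes left out, so a shift that depends on signal level stays open. RNA splicing, with 16 of 146 genes higher and 2 lower (camera adjusted p = 1.11e-06; adjusted p = 0.852 with an estimated correlation), had an adjusted p of 0.172 without saline replicates 1 and 2.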
